A study of Rattus norvegicus with 16 samples.

How the data were processed

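The series holds 16 Affymetrix arrays of rat mammary gland RNA, with 2 arrays for each of 8 groups of treatment (control, genistein, vinclozolin, mixture) and age (PND35, PND50). Per the labels' protocols, dams were randomised into groups of 15 and gavaged from gestational day 1 to PND 21, RNA was extracted from individual glands, and each array carried a pool of RNA from 5 animals. The groups and replicate numbers were taken from the sample titles.

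The table of values deposited by the authors gives 1 number for each of 27342 probe sets and 16 arrays. The deposited values lie between 2.2 and 13.9 and were read as log2 intensities from that range, since the log base, background correction, normalization, summarization and annotation are not given in the sources used here. The array medians lay between 7.05 and 7.145, and no further normalization was applied in the main analysis. No detection calls were used here, so a dim probe set was judged by its value alone.

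Probe sets were named through a table of the platform's annotation. It lists 15420 of the probe sets, 15097 of them with exactly 1 gene symbol and 323 with several, and the other 11922 are unnamed here. Gene identifiers of 15067 matched a RefSeq gene table of the assembly GRCr8, used for names only, and 30 kept the annotation's symbol. No coordinates are printed. Where a symbol had several probe sets, as 499 of the 14324 symbols had, the probe set with the highest mean over all arrays was kept. Genes whose mean lay under the 25th percentile of all probe sets (5.661 on the log2 scale) were left out, which left 11796 genes.

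Tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes on 1 mean per group over all 16 arrays, 8 residual degrees of freedom and contrasts of the group means. All tests were two-sided, p-values were adjusted by Benjamini and Hochberg's method over the genes of a comparison, and the threshold was an adjusted p of 0.05. There were 16 comparisons. The 28 gene lists held 518 genes, of which 443 were named on the array and 423 tested, and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Alternatives for lists were camera with an estimated correlation and fry, and calls at the preset correlation are to be read with the estimated value given beside them. With an estimated correlation, the only call among the 8 main comparisons was the skin keratinocyte list with vinclozolin at PND35. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

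Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest genes past the threshold whose pools did not overlap between the groups compared, within each treatment or age that a comparison averages, without placeholder symbols. Where fewer than 5 passed in a direction, it took the 5 genes with the smallest p among those with at least a 1.5-fold change and no overlap, given as not passing. It added up to 4 genes per described list and a fixed panel of genes, of which Mki67 is unnamed on the array here and Tnfsf11 lay under the filter. Some genes were not used here. Genes of the rule that are not printed stand in the same tables. Krt25 in the averages, and Krt25 and Krt17 in the mixture against the sum, were chosen after their comparison was seen.

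The alternatives fixed beforehand were no filter and a filter at the 50th percentile, quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, a replicate block, array weights, an intensity trend with a robust fit, other thresholds, smaller sets of arrays, and each pool left out in turn. Added after the data were seen were both vinclozolin PND35 pools left out, a muscle score as a covariate, and hair and epidermal genes left out. The list of hair and epidermal genes was written after those genes had been seen at the top of the vinclozolin result, so its counts are not independent evidence.

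The fits were tested on simulated data with changed genes added to unchanged ones and normal noise of the size measured here. For vinclozolin against control at PND35, 71.8% of log2 changes of 0.5 and 97.8% of changes of 1 were recovered, with 4.27% of calls false. For the age average 97.3% and 99.4% were recovered. In 20 simulations without change, camera at the preset correlation made 3 false list calls. The simulated genes vary independently of each other, so these figures do not cover lists whose genes vary together, as the estimated correlations of up to 0.852 show they do here. All pools of a gene were simulated with the same noise. The vinclozolin PND35 pools differed more from each other (SD of the difference 0.303) than the pools of the other groups (0.17 to 0.206). The 4.27% is therefore not the error rate of the calls made in that comparison.

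In the tests of explanations in the closing section, the rule for excluding an explanation was tightened after the first values were seen: an opposite sign had to lie outside the overlap of pools, and a correlation had to lie below its bound with its whole interval. This turned 4 verdicts of exclusion into open ones and none the other way.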

Results

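Mammary glands of female Wistar Han rats were profiled on Affymetrix arrays at postnatal day (PND) 35 and PND 50. Their mothers had been gavaged daily from gestational day 1 to weaning at PND 21 with genistein, with vinclozolin, with both, or with neither. Genistein is a soy isoflavone that binds estrogen receptors, and vinclozolin is a fungicide with antiandrogenic action. Each compound was given at 1 mg per kg body weight per day, also in the mixture. The 8 groups of treatment and age held 2 arrays each, and each of the 16 arrays carried a pool of RNA from 5 animals. Replicates of a group correlated between 0.9893 and 0.9966 over all probe sets, with the lowest value for the vinclozolin pools at PND35. The number of arrays limits the precision of every comparison, and p-values measure the spread between pools, not between animals. The median standard error of a log2 fold change was 0.0941 for a comparison of 2 groups and 0.0471 for the age comparison averaged over treatments.

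The comparison of ages, averaged over the 4 treatments, asked how the gland changed between PND35 and PND50. Cd7, a surface protein of T and natural killer cells, rose 2.83-fold (SE 0.07 on the log2 scale, n = 8 pools per age, adjusted p = 5.84e-07). On that scale Tacr1, the receptor of substance P, rose by 1.43 (SE 0.09), Tf, which encodes transferrin, by 1.14 (SE 0.07), and Jchain, which joins immunoglobulin units, by 1.01 (SE 0.08). Alox15, a lipoxygenase of arachidonic acid, fell by 2.36 (SE 0.16, adjusted p = 7.85e-06). Slc4a1, the anion exchanger of red cells, fell by 1.31 (SE 0.14), Alas2, the erythroid enzyme that starts haem synthesis, fell by 1.24 (SE 0.12), and the globin gene Hbb fell by 1.11 (SE 0.10). In all, 2289 genes were higher and 2972 lower of the 11796 tested.

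Gene lists fixed before the data were examined moved as groups with age. All 25 measured proliferation genes were lower at PND50 (mean log2 fold change -0.56), and 23 of them fell, or 25 adjusted over the list alone. Bub1b and Kif11, which act in mitosis, both fell by 0.71 (SE 0.09 and 0.10), and Tyms, an enzyme of thymidylate synthesis, fell by 0.45 (SE 0.05). The list passed limma's camera test (adjusted p = 3.02e-08), but not with an estimated correlation (adjusted p = 0.511 with an estimated correlation). All 23 oxidative phosphorylation genes were lower (mean -0.23, adjusted p = 2.18e-07; adjusted p = 0.511 with an estimated correlation), and 20 fell, also 20 adjusted over the list alone. Ndufb5, a subunit of complex I, fell by 0.32 (SE 0.04) and Sdha, a subunit of complex II, fell by 0.37 (SE 0.06). Of 20 luminal epithelium genes 13 rose and none fell, or 14 and none adjusted over the list alone (mean 0.25, adjusted p = 2.12e-05; adjusted p = 0.511 with an estimated correlation). Elf5, a transcription factor of alveolar cells, rose by 0.61 (SE 0.07) and Gata3, a luminal transcription factor, by 0.44 (SE 0.06).

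Milk genes were among the higher ones at PND50. Of 18 milk protein and secretion genes 12 rose and 1 fell, or 13 and 1 adjusted over the list alone (mean 0.35, adjusted p = 1.45e-05; adjusted p = 0.511 with an estimated correlation). Btn1a1, which encodes the butyrophilin of the milk fat globule, rose by 0.79 (SE 0.06) and Lalba, which encodes alpha-lactalbumin, by 0.59 (SE 0.06). The milk protein genes Csn2 (0.34, SE 0.49, adjusted p = 0.587) and Wap (0.51, SE 0.20, adjusted p = 0.0565) did not pass the limma test. In the control groups alone they had -0.45 (SE 0.98) and -0.38 (SE 0.40), also not past it. All 12 lymphocyte genes were higher (mean 0.26, adjusted p = 4.61e-05; adjusted p = 0.511 with an estimated correlation), and 8 rose, or 10 adjusted over the list alone. Cd3e, a part of the T cell receptor complex, rose by 0.77 (SE 0.05). Of 20 adipocyte genes 8 fell and none rose, with the same counts adjusted over the list alone (mean -0.21, adjusted p = 0.0153; adjusted p = 0.511 with an estimated correlation). Cd36, a fatty acid transporter, fell by 0.41 (SE 0.08). The adipocyte call was lost with the 50th percentile as filter and with the muscle score as a covariate (adjusted p up to 0.326).

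Skeletal muscle genes were lower at PND50 too. All 19 had a negative log2 fold change (mean -1.20, SD over members 0.56), and 15 fell, or 16 adjusted over the list alone (adjusted p = 1.02e-05; adjusted p = 0.511 with an estimated correlation). Myh4, a fast myosin heavy chain, fell by 1.94 (SE 0.33) and Pvalb, which encodes parvalbumin, fell by 1.88 (SE 0.24). The muscle score of a pool, its mean centred log2 value over the list, lay between -0.09 and 2.15 at PND35 and between -1.88 and 1.24 at PND50. With that score as a covariate, a choice made after seeing the data, the age comparison called 148 genes in place of 5261; the score itself differs between the ages.

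**Figure D1:**
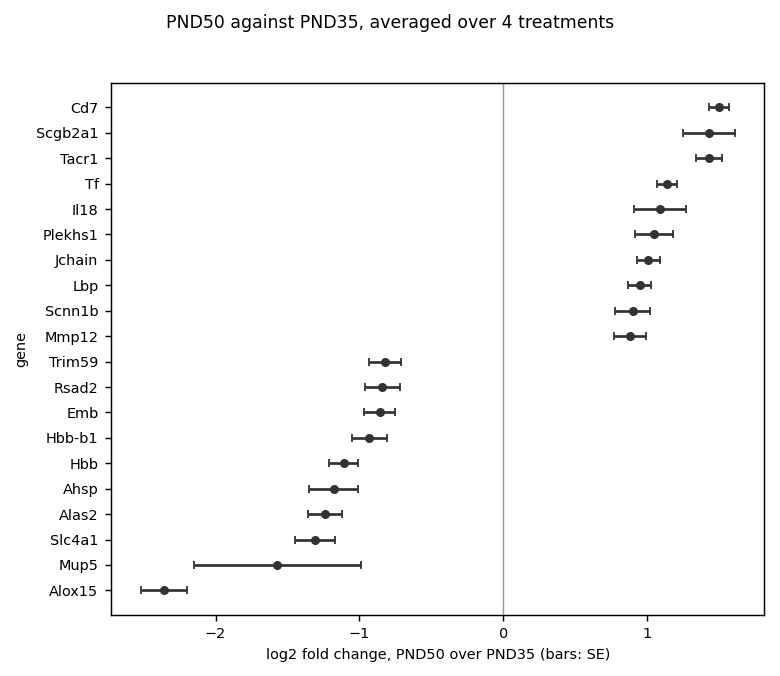
Log2 fold change at PND50 over PND35, averaged over the 4 treatments, for the 10 highest and 10 lowest genes past the test whose pools did not overlap between ages within any treatment. Points are estimates and bars are standard errors; Tacr1 stands at 1.43 and Alox15 at -2.36.

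In the control groups alone, 74 genes were higher and 28 lower at PND50. Cd7 rose by 1.70 (SE 0.14, n = 2 pools per age, adjusted p = 0.000988), Tacr1 by 1.46 (SE 0.18) and Anxa8, an annexin, by 1.28 (SE 0.15). Alox15 fell by 1.97 (SE 0.31), Epha3, an ephrin receptor, fell by 1.00 (SE 0.15), and Hdc, the enzyme that makes histamine, fell by 0.69 (SE 0.09). All 20 luminal epithelium genes were higher (mean 0.41, adjusted p = 1.91e-11; adjusted p = 0.437 with an estimated correlation), but 2 rose genome-wide and 15 adjusted over the list alone. Ehf, an epithelial transcription factor, rose by 0.70 (SE 0.13). Of 14 basal and myoepithelial genes 2 rose, or 8 adjusted over the list alone (mean 0.36, adjusted p = 1.38e-06; adjusted p = 0.437 with an estimated correlation), among them Cnn1, a calponin of contractile cells, by 0.72 (SE 0.12). Of 10 mast cell genes 2 fell, or 7 adjusted over the list alone, where 1 other rose. The list mean was -0.32 (camera, adjusted p = 0.000755, and 0.484 with an estimated correlation). In the average over treatments the mast cell list did not pass camera (mean -0.20, adjusted p = 0.0852), though it passed fry (adjusted p = 0.0134). The muscle list had a mean of -1.13 in the controls alone. The count of 102 genes was 41 without control PND35 replicate 1, 2 without control PND35 replicate 2, 3 without control PND50 replicate 1 and 10 without control PND50 replicate 2. It was 175 without either vinclozolin PND35 pool, 177 without either genistein PND35 pool, 49 without either mixture PND35 pool, 53 without either vinclozolin PND50 pool and 47 without either mixture PND50 pool. All 102 genes were also called, in the same direction, in the average over treatments, which holds the same control pools.

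Vinclozolin at PND35 was compared with its control to ask what exposure before weaning left in the pubertal gland. The highest genes were keratins and other genes of the hair follicle. Krt25, a keratin of the inner root sheath, rose by 5.53 on the log2 scale (SE 0.12, n = 2 pools per group, adjusted p = 2.94e-10), from 4.98 and 5.03 in the control pools to 10.48 and 10.59. Krtap15-1, a keratin-associated protein, rose by 5.04 (SE 0.35), Krt73 by 4.28 (SE 0.17), Krt27 by 4.09 (SE 0.10) and Dsg4, a desmosomal cadherin of the hair shaft, by 3.30 (SE 0.20). The control values of Krt25, Krtap15-1, Krt27 and Dsg4 lay under the filter value of 5.661, so their changes are lower bounds if those probe sets measured only background there. In the mixture pools of the same age, which received the same vinclozolin dose, Krt25 stood at 5.36 and 4.86. In all, 114 genes were higher and 44 lower. Of the 114 higher genes, 41 were keratins or belonged to a list of hair and epidermal genes drawn up after the result was seen, and 73 were not.

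The skin keratinocyte list, fixed beforehand, was higher in the vinclozolin pools. All 6 measured members were positive (mean log2 fold change 0.85), and 2 rose, or 4 adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 5.48e-09) and with an estimated one (adjusted p = 0.00619 with an estimated correlation). Of its 16 genes 9 were named and 6 passed the filter. The filter mean includes the vinclozolin pools, so dim members that did not rise could drop out. Sbsn, a protein of the cornified epidermis, rose by 1.43 (SE 0.08) and Trex2 by 1.07 (SE 0.10). The skin score was 0.93 and 0.48 in the vinclozolin pools and lay between -0.22 and 0.02 in the other 14. Basal and myoepithelial genes were higher beside it: 2 of 14 rose, or 7 adjusted over the list alone (mean 0.54, adjusted p = 8.97e-10; adjusted p = 0.087 with an estimated correlation). Those 2 were Krt17, by 2.74 (SE 0.21), and Krt14, by 1.85 (SE 0.27), keratins that are also made in epidermis and hair follicles. Of 20 luminal epithelium genes 2 rose, or 14 adjusted over the list alone. The list mean was 0.42 (camera, adjusted p = 6.47e-14, and 0.144 with an estimated correlation). Ovol1, an epithelial transcription factor, rose by 1.28 (SE 0.11). Whether Ovol1 and the list rose in mammary epithelium or in skin was not tested.

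Macrophage, mast cell, adipocyte and endothelial genes were lower with vinclozolin at PND35, and the lymphocyte list was not called (mean -0.03, adjusted p = 0.998). Of 17 macrophage genes 3 fell, or 12 adjusted over the list alone (mean -0.35, adjusted p = 5.48e-09; adjusted p = 0.14 with an estimated correlation). Itgam, an integrin of myeloid cells, fell by 0.58 (SE 0.11), and C1qb, a complement component, fell by 0.58 (SE 0.12). Hdc fell by 0.61 (SE 0.09) and Il1rl1, the receptor of interleukin 33, fell by 0.58 (SE 0.10). Of 10 mast cell genes 9 were negative (mean -0.24, adjusted p = 0.00211; adjusted p = 0.318 with an estimated correlation), and 1 fell, or 3 adjusted over the list alone, where 1 other rose. Of 20 adipocyte genes 19 were negative (mean -0.23, adjusted p = 0.00249; adjusted p = 0.542 with an estimated correlation), with 0 past the test genome-wide and 1 adjusted over the list alone. Of 11 endothelial genes 10 were negative (mean -0.18, adjusted p = 0.0189; adjusted p = 0.542 with an estimated correlation), with 0 past the test on either scale of adjustment. The mast cell call was lost without vinclozolin PND35 replicate 1 (mean -0.17, adjusted p = 0.124). The adipocyte and endothelial calls were lost without vinclozolin PND35 replicate 2 (means -0.0188 and -0.0589) and without control PND35 replicate 2 (means -0.12 and -0.13). Their means were -0.44 and -0.30 without vinclozolin PND35 replicate 1. Macrophage and mast cell lists were also called lower with genistein and with the mixture, against the same 2 control pools. With the mixture the means were -0.17 and -0.15 (camera, adjusted p = 0.00122 and 0.0366, and 0.836 for both with an estimated correlation). Hdc stood at 8.45 and 8.49 in those control pools and between 7.86 and 8.07 in the exposed pools of this age. These falls are thus not particular to vinclozolin and share the same controls.

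Of 13 cholesterol synthesis genes 1 rose, or 5 adjusted over the list alone (mean 0.42, adjusted p = 0.00059; adjusted p = 0.318 with an estimated correlation). It was Sqle, squalene epoxidase, up by 0.47 (SE 0.09). The cholesterol mean was 0.18 without vinclozolin PND35 replicate 2 and 0.655 without replicate 1. Fibrous matrix genes were all negative, and 1 of 17 fell, or 4 adjusted over the list alone (mean -0.19, adjusted p = 3.46e-06; adjusted p = 0.318 with an estimated correlation), and the mean was -0.11 without vinclozolin PND35 replicate 2. The count of 158 genes became 844 without vinclozolin PND35 replicate 1, 66 without control PND35 replicate 1 and 54 without control PND35 replicate 2, and 71 with hair and epidermal genes left out, a choice made after seeing the data.

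**Figure D2:**
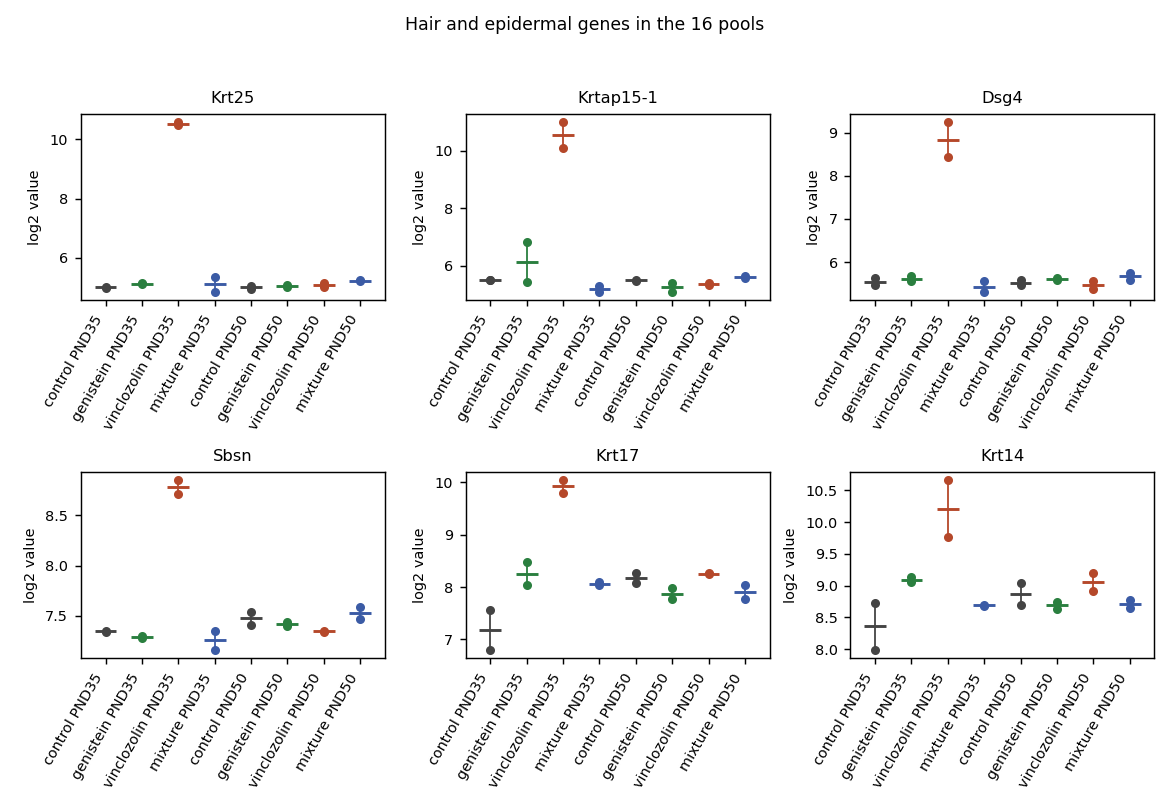
Deposited log2 values of 6 hair and epidermal genes in the 16 pools. Points are pools, horizontal bars are group means; both vinclozolin PND35 pools lie above all others for each of the 6 genes, with Krt25 at 10.48 and 10.59.

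Genistein at PND35 was compared with the same control pools, and no gene passed the limma test (smallest adjusted p = 0.232; 1311 genes at an unadjusted p under 0.05, 590 expected by chance). Among genes that did not pass, Krt17 had a log2 fold change of 1.07 (SE 0.21, adjusted p = 0.232), Elf5 0.65 (SE 0.13), Acsm3 2.07 (SE 0.48) and Cxcl3, a chemokine, -0.89 (SE 0.17). All 20 luminal epithelium genes were positive (mean 0.40, adjusted p = 1.16e-13; adjusted p = 0.2 with an estimated correlation), with 0 genome-wide and 16 adjusted over the list alone. Cldn3, a tight junction protein, had 0.45 (SE 0.10). Of 14 basal and myoepithelial genes 13 were positive, and 7 rose adjusted over the list alone and 0 genome-wide (mean 0.33, adjusted p = 1.07e-06; adjusted p = 0.2 with an estimated correlation), with a mean of 0.205 without genistein PND35 replicate 1. Of 17 macrophage genes 15 were negative, and 5 fell adjusted over the list alone and 0 genome-wide (mean -0.25, adjusted p = 2.73e-10; adjusted p = 0.2 with an estimated correlation). Of 20 adipocyte genes 18 were negative (mean -0.16, adjusted p = 4.1e-05; adjusted p = 0.532 with an estimated correlation), with 0 past the test on either scale of adjustment. The adipocyte mean was -0.26 without control PND35 replicate 1 and -0.05 without replicate 2, where the call was lost (adjusted p = 0.0912). The luminal score was -0.27 and -0.41 in the control pools that the 3 exposures share at this age, and -0.29 in both mixture pools. The gene count was 58 without genistein PND35 replicate 2 and 1 without either genistein PND50 pool.

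The mixture at PND35 called no gene with limma either (smallest adjusted p = 0.106; 1799 genes at an unadjusted p under 0.05). Among genes that did not pass, Lcp2, an adaptor of immune cell signalling, had a log2 fold change of -0.66 (SE 0.11, adjusted p = 0.106), Myh7, the slow myosin heavy chain, 1.00 (SE 0.21), and Wap, which encodes whey acidic protein, -1.27 (SE 0.40). All 19 muscle genes were positive (mean 1.23, adjusted p = 1.47e-09; adjusted p = 0.836 with an estimated correlation), 5 of them past the test adjusted over the list alone and 0 genome-wide. The muscle score was 0.77 and 2.15 in the mixture pools against 0.16 and 0.29 in the controls, and the list mean was 1.92 and 0.54 without mixture PND35 replicates 1 and 2. All 25 proliferation genes were positive beside it (mean 0.35, adjusted p = 9.23e-06; adjusted p = 0.884 with an estimated correlation), with 0 past the test on either scale of adjustment and a mean of 0.23 without control PND35 replicate 2. Of 18 milk genes 16 were negative (mean -0.41, adjusted p = 0.00107; adjusted p = 0.836 with an estimated correlation), and 4 fell adjusted over the list alone and 0 genome-wide. The gene count was 24 without mixture PND35 replicate 1 and 1 without either genistein PND50 pool.

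At PND50 the exposures were compared with their own controls to ask what remained in the gland of older animals. With genistein no gene passed (smallest adjusted p = 1; 307 genes at an unadjusted p under 0.05, fewer than the 590 expected by chance). Pfkfb3, a regulator of glycolysis, had a log2 fold change of 0.83 (SE 0.26) and Gpr37 -0.62 (SE 0.17), both with an adjusted p of 1. Of 17 fibrous matrix genes 16 were positive (mean 0.09, adjusted p = 0.000162; adjusted p = 0.777 with an estimated correlation), and of 14 basal genes 12 were negative (mean -0.14, adjusted p = 0.00158; adjusted p = 0.777 with an estimated correlation). No member of either list passed, genome-wide or adjusted over the list alone. The matrix mean was 0.145 without genistein PND50 replicate 1 and 0.04 without replicate 2, where the call was lost (adjusted p = 0.247). Without genistein PND50 replicate 1 the gene count was 1.

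With vinclozolin at PND50 no gene passed (smallest adjusted p = 0.798; 713 genes at an unadjusted p under 0.05). Slc34a2, a phosphate transporter, had a log2 fold change of 1.21 (SE 0.23, n = 2 pools per group), Wap 1.43 (SE 0.40) and Retnlg -0.62 (SE 0.12), each with an adjusted p of 0.798. All 19 muscle genes were positive (mean 1.54, adjusted p = 1.05e-19; adjusted p = 0.447 with an estimated correlation), 16 of them past the test adjusted over the list alone and 0 genome-wide. The muscle score was 1.24 and 0.03 in the vinclozolin pools against -0.83 and -0.98 in the controls, and the list mean was 0.93 without vinclozolin PND50 replicate 1. Of 18 milk genes 15 were positive beside it (mean 0.61, adjusted p = 6.07e-09; adjusted p = 0.438 with an estimated correlation), 2 of them past the test adjusted over the list alone and 0 genome-wide. The median over the milk list was 0.265, under its mean, which a few genes carry in part. One was Csn2, at 11.26 and 11.69 in the vinclozolin pools and 8.07 and 10.45 in the controls. The milk score was -0.22 and 0.45 in the control pools, and the mean was 0.28 and 0.95 without control PND50 replicates 1 and 2. All 25 proliferation genes were positive (mean 0.34, adjusted p = 9.14e-10; adjusted p = 0.546 with an estimated correlation), with 0 past the test on either scale of adjustment. That mean rested on 1 control pool: it was 0.00908 without control PND50 replicate 1, where the call was lost (adjusted p = 0.648), and 0.67 without replicate 2. Of 17 macrophage genes 15 were negative (mean -0.20, adjusted p = 2.2e-05; adjusted p = 0.46 with an estimated correlation), and Clec10a, a lectin of macrophages, had -0.44 (SE 0.10, adjusted p = 0.798).

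With the mixture at PND50 only Met passed the limma test. Met, the receptor of hepatocyte growth factor, rose by 0.51 (SE 0.06, n = 2 pools per group, adjusted p = 0.046), from 9.11 and 9.09 to 9.60 and 9.62. Genes just short of the threshold were Slc5a8, a transporter of short-chain fatty acids, with 1.39 (SE 0.19, adjusted p = 0.0508), and Slc4a4, a bicarbonate transporter, with 0.64 (SE 0.09, adjusted p = 0.0508). Reg3b, a secreted lectin, had 1.83 (SE 0.29, adjusted p = 0.125) and Areg, which encodes the EGF receptor ligand amphiregulin, -1.04 (SE 0.26, adjusted p = 0.434). All 25 proliferation genes were negative (mean -0.45, adjusted p = 8.58e-10; adjusted p = 0.772 with an estimated correlation), with 0 past the test on either scale of adjustment. The proliferation score was -0.63 and -0.69 in the mixture pools and -0.54 and 0.12 in the control pools. The proliferation mean was -0.12 without control PND50 replicate 2, where the call was lost (adjusted p = 0.219), and -0.775 without replicate 1. Of 19 interferon response genes 15 were positive (mean 0.34, adjusted p = 0.000197; adjusted p = 0.772 with an estimated correlation), 1 past the test adjusted over the list alone, and the score was 0.12 and 0.73 in the mixture pools against 0.24 and -0.08 in the controls. The interferon call was lost without mixture PND50 replicate 2 (mean 0.04, adjusted p = 0.936) and without control PND50 replicate 2 (mean 0.185, adjusted p = 0.0783), and the mean was 0.65 without mixture PND50 replicate 1. The call of Met was lost without any single pool of the mixture at either age, of the controls at PND50, or of genistein or vinclozolin at PND50, and with the muscle score as a covariate, where the count was 0. The count was 2 without either control PND35 pool and 6 without either genistein PND35 pool.

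**Figure D3:**
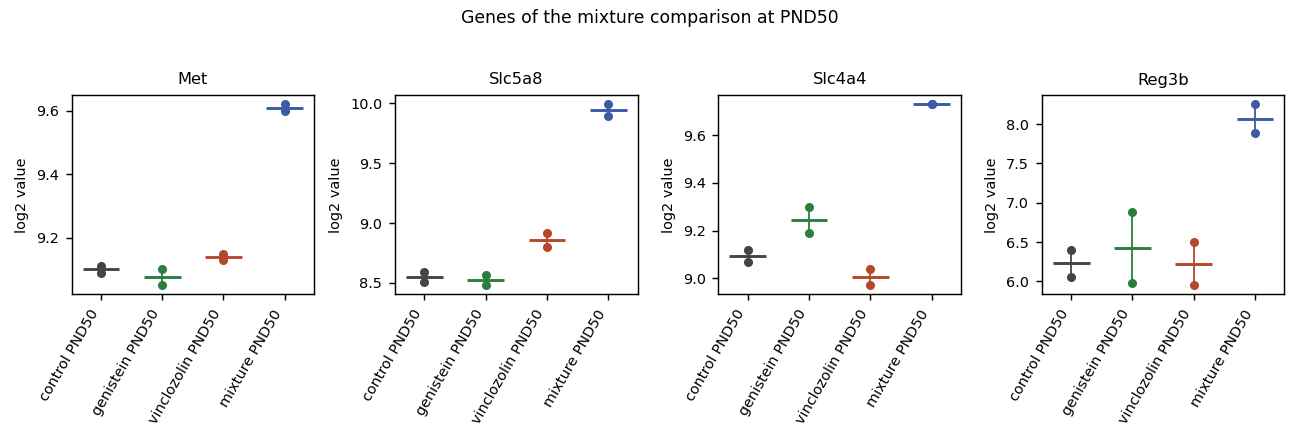
Deposited log2 values at PND50 of Met, Slc5a8, Slc4a4 and Reg3b in 4 groups of 2 pools. Points are pools and horizontal bars are group means; Met stood at 9.60 and 9.62 in the mixture pools, and of the 4 genes only Met passed the test.

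**Figure D4:**
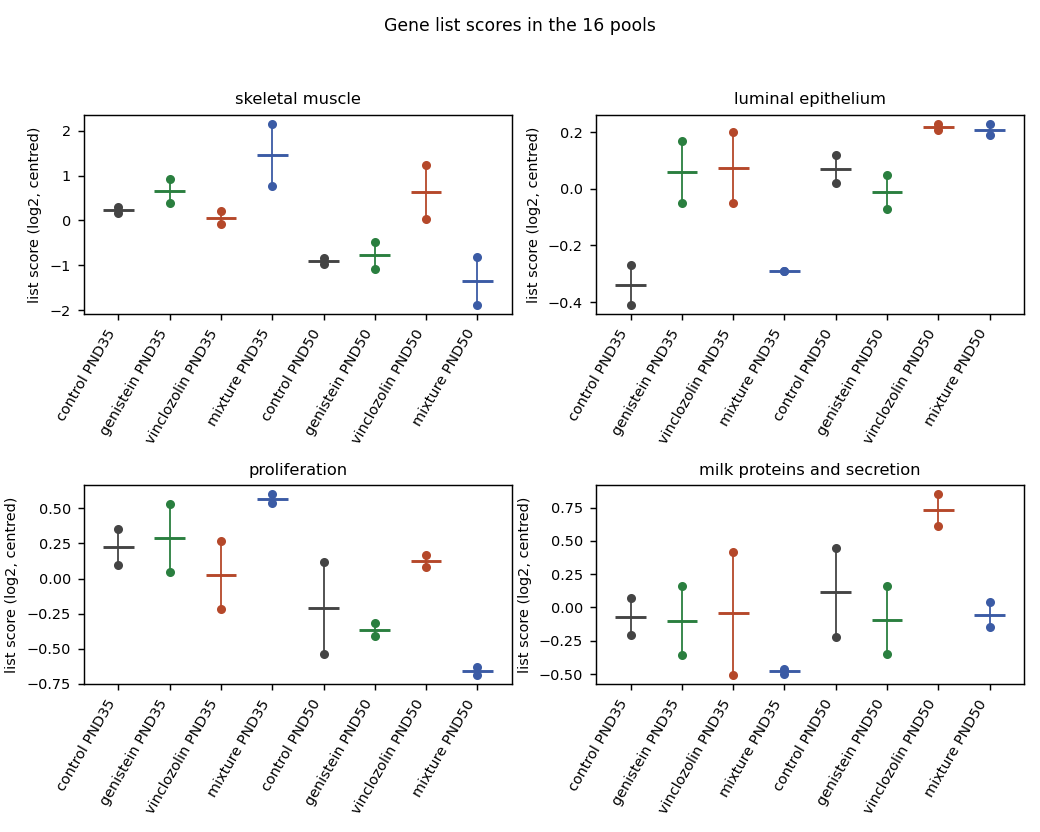
Scores of 4 gene lists in the 16 pools, each the mean centred log2 value over the list. Points are pools and horizontal bars are group means; the muscle score of the mixture at PND35 was 0.77 in one pool and 2.15 in the other.

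Averaged over both ages, 60 genes were higher and 33 lower with vinclozolin, while genistein and the mixture called 0 each with limma (667 and 1240 genes at an unadjusted p under 0.05). Of the 158 genes called with vinclozolin at PND35, 77 were called in the same direction in this average, which holds the same PND35 pools. Krt25 had 2.81 there (SE 0.09, adjusted p = 1.36e-08), with 5.53 at PND35 and 0.08 at PND50. The average called 19 genes with hair and epidermal genes left out, 815 without vinclozolin PND35 replicate 1, 51 and 43 without control PND35 replicates 1 and 2, 39 and 54 without control PND50 replicates 1 and 2, and 40 without vinclozolin PND50 replicate 1. Without genistein PND50 replicate 1 the genistein average called 1 gene, and without mixture PND35 replicate 1 the mixture average called 7.

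The mixture was set against the sum of its components at each age to ask whether the compounds acted additively. At PND35, 38 genes were higher and 147 lower than the sum. Krt25 differed from the sum by -5.56 (SE 0.18, adjusted p = 1.52e-08), and Krt17 by -2.93 (SE 0.30, adjusted p = 0.000296). Of the 158 genes called with vinclozolin alone at this age, 104 were called here with the opposite sign. This comparison subtracts the vinclozolin effect measured in the same vinclozolin and control pools. An opposite sign is thus favoured in advance, and the count is not independent evidence. The skin keratinocyte list was lower (mean -0.94, adjusted p = 4.91e-06; adjusted p = 0.0293 with an estimated correlation), with 2 of 6 members falling, or 4 adjusted over the list alone. Of 20 luminal genes 7 fell, or 19 adjusted over the list alone (mean -0.77, adjusted p = 4e-17; adjusted p = 0.119 with an estimated correlation). The count of 185 was 764 and 122 without vinclozolin PND35 replicates 1 and 2, 53 and 405 without genistein PND35 replicates 1 and 2, 111 and 49 without mixture PND35 replicates 1 and 2, 98 and 54 without control PND35 replicates 1 and 2, and 123 without either mixture PND50 pool. At PND50 no gene passed with limma (smallest adjusted p = 0.554; 768 genes at an unadjusted p under 0.05), and 1 did without genistein PND50 replicate 1.

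The effects of 2 exposures were also correlated across genes, which are not independent replicates. At PND35 Pearson's r was 0.421 for genistein and vinclozolin, 0.52 for genistein and the mixture and 0.128 for vinclozolin and the mixture. With 1 control pool for each exposure these were 0.212, 0.225 and -0.0105. For genistein and the mixture r was 0.273 without genistein PND35 replicate 2. For vinclozolin and the mixture it was 0.239 and 0.231 without control PND35 replicates 1 and 2, 0.0667 without vinclozolin PND35 replicate 2 and 0.0712 without mixture PND35 replicate 1. Unchanged groups simulated against the same controls gave 0.5 for each pair, so part or all of these values may come from the shared controls, which could not be split into sets of 2. The covariance was 0.0166 against a simulated 0.00812 for genistein and vinclozolin, a difference of 0.00849, and differed by 0.00579 and -0.00209 for the other pairs. At PND50 r was 0.194, 0.34 and 0.0767 (with 1 control pool each -0.109, -0.0785 and -0.126; single pools left out 0.0627 to 0.504, 0.169 to 0.615 and -0.0667 to 0.32), with covariance differences of -0.00463, -0.00268 and -0.00623. Between ages, with no shared pools, r was -0.0562 for genistein, 0.0845 for vinclozolin and -0.0732 for the mixture. Over single pools left out they ranged from -0.162 to 0.0771, from -0.0729 to 0.182 and from -0.147 to 0.0379. For genistein the sign changed without control PND35 replicate 2 (0.0771), control PND50 replicate 2 (0.0485) or genistein PND50 replicate 1 (0.0451), for vinclozolin without vinclozolin PND35 replicate 2 (-0.0729), and for the mixture without control PND35 replicate 2 (0.00839) or mixture PND50 replicate 2 (0.0379).

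Hormone receptors and growth factors of a fixed panel did not pass in any exposure comparison at a single age. Esr1, the estrogen receptor alpha gene, had a log2 fold change of -0.27 with genistein (SE 0.13, adjusted p = 0.481), -0.31 with vinclozolin (SE 0.13, adjusted p = 0.316) and -0.30 with the mixture (SE 0.13, adjusted p = 0.319) at PND35. Pgr, the progesterone receptor gene, had 0.25, -0.01 and 0.27 (SE 0.32 for each). Igf1, which encodes a growth factor, had -0.19 with genistein (SE 0.07, adjusted p = 0.347), -0.17 with vinclozolin (SE 0.07, adjusted p = 0.271) and -0.16 with the mixture (SE 0.07, adjusted p = 0.288). The estrogen-responsive list was not called with vinclozolin at PND35 (mean -0.08, adjusted p = 0.341), nor was the androgen-responsive list (mean 0.05, adjusted p = 0.998).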

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

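Vinclozolin effects that differed between PND35 and PND50 in a test of the difference, and signal in probe sets that the gene comparisons do not use, were examined further. Of the tests below, the one of sebaceous genes was set before its result was seen, and the one of the mixture dose was chosen after.

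The effect of vinclozolin differed between the ages for 45 genes, all lower at PND50 than at PND35, with 0 higher (limma, 792 genes at an unadjusted p under 0.05). All 45 were among the 158 genes called with vinclozolin at PND35, with the opposite sign. The PND35 effect of the same pools is subtracted here, so an opposite sign is favoured in advance and the 45 are not independent evidence. The genes named below are among the 10 highest at PND35. The count was 10 with hair and epidermal genes left out, and 186 and 77 without vinclozolin PND35 replicates 1 and 2. For Krt25 the difference was -5.45 on the log2 scale (adjusted p = 1.9e-08), from 5.53 at PND35 to 0.08 at PND50. For Krtap15-1 it was -5.16 (adjusted p = 0.000192), for Krt73 -4.41 (adjusted p = 1.13e-06), for Krt72 -4.27 (adjusted p = 6.7e-06) and for Krt27 -4.03 (adjusted p = 4.04e-08). For Krtap1-5 it was -3.55 (adjusted p = 0.000151), for S100a3 -3.34 (adjusted p = 4.51e-05), for Krt31 -3.60 (adjusted p = 0.000151) and for Dsg4 -3.36 (adjusted p = 5.98e-05). The skin keratinocyte list differed by -0.932 (adjusted p = 0.00621 with an estimated correlation), from 0.854 to -0.0777.

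Of 8033 probe sets without a single gene symbol, 97 were higher with vinclozolin at PND35 when all 20506 probe sets were tested. Which genes they measure was not analysed here.

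Hair and epidermal genes were higher in both vinclozolin PND35 pools: all 8 measured inner root sheath genes rose (median log2 fold change 3.58), 13 of 15 hair shaft and matrix genes (median 1.99) and 11 of 16 epidermal genes (median 1.57). Measured genes are those of 11, 22 and 31 listed that were named and passed the filter. The filter mean includes the vinclozolin pools, so genes that did not rise could drop out, and these shares are partly fixed by it. Dsg4, for example, stood at 9.25 and 8.43 in those pools and between 5.31 and 5.75 in all others. The vinclozolin dose alone is argued against as the cause, since the mixture held the same dose. The 23 hair shaft and inner root sheath genes had a median of -0.10 there against 2.44 with vinclozolin. Mixture pools lay below vinclozolin pools for 100% of them. The 2.44 and the 100% are partly fixed, since the list followed the vinclozolin result and the filter mean includes those pools. The skin keratinocyte list, fixed beforehand but also filtered, had a mean of -0.03 in the mixture against 0.85 with vinclozolin. Skin carried into the dissected glands may be the source, and its predicted value was present: sebaceous genes had a median of 0.44, at the 99.83 percentile of random lists matched on mean expression. The lists were not matched on spread, and the SEs of the 4 genes lay between 0.15 and 0.44, against a median of 0.0941 over all genes. The percentile therefore cannot decide the question. The median of 0.44 rests on Mc5r (0.92, adjusted p = 0.201) and Fa2h (1.06, adjusted p = 0.295), while Awat1 (-0.04) and Mogat2 (-0.19) did not move with them, and none of the 4 passed alone. The 1 measured melanocyte gene had -0.08. An effect of vinclozolin that genistein offsets stays open: the mixture lay below the sum of its components (Krt25 -5.56, adjusted p = 1.52e-08), which skin in the vinclozolin pools alone would give as well.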

How the results depend on the processing

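Counts of genes are given here where they left a range of 1.5 times the main count; the cause was not tested unless stated. Main counts were 102 for age in controls, 5261 for the age average, 158 for vinclozolin at PND35, 1 for the mixture at PND50, 93 for the vinclozolin average, 185 for the mixture against the sum at PND35, 45 for the difference between ages with vinclozolin, and 0 elsewhere.

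Without a filter the mixture called 1 gene at PND35, 6 at PND50 and 2 for the difference between ages. With the 50th percentile as filter, which tests fewer genes, vinclozolin called 94 at PND35, 45 averaged and 11 for the difference between ages, and the mixture called 3 at PND50. Quantile normalization, median centring, and an intensity trend with a robust fit each gave 2 for the mixture at PND50. All probe sets, which are more tests, gave 255 for age in controls, 8624 for the age average, 273 for vinclozolin at PND35, 0 for the mixture at PND50, 165 for the vinclozolin average, 284 for the mixture against the sum at PND35 and 98 for the difference between ages with vinclozolin. Array weights gave 375 for age in controls, 104 for vinclozolin at PND35 and 7 for the mixture at PND50.

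An unadjusted p under 0.01 with a 1.5-fold change, a threshold without adjustment, gave 192 for the age average. At PND35 it gave 28 for genistein, 27 for the mixture and 374 for the mixture against the sum. At PND50 it gave 2 for genistein, 32 for vinclozolin, 28 for the mixture and 48 for the mixture against the sum. Averaged over ages it gave 1, 56 and 6 for genistein, vinclozolin and the mixture, and for their differences between ages 50, 121 and 83. An adjusted p under 0.1 gave 348 for age in controls, 329 for vinclozolin at PND35, 3 for the mixture at PND50, 237 for the vinclozolin average and 420 for the mixture against the sum at PND35. With only the 8 arrays of an age, vinclozolin called 49 and the mixture against the sum 33 at PND35, and genistein called 1 and the mixture 6 at PND50. With only the 4 arrays compared, the counts were 176 for age in controls, 25 for vinclozolin at PND35 and 5 for the mixture at PND50.

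The replicate numbers do not show that samples are paired: over 28 pairs of groups, replicate differences correlated between -0.366 and 0.301, 8 of them over 0.1. A replicate block gave 1 for vinclozolin at PND50, 4 for the mixture at PND50 and 1 for the mixture against the sum at PND50.

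In settings chosen after seeing the data, age in controls called 175 without both vinclozolin PND35 pools. With a muscle score as a covariate it called 4, the age average 148, the mixture at PND50 0, the vinclozolin average 42 and the mixture against the sum at PND35 72; the score is tied to age. With hair and epidermal genes left out, vinclozolin called 71 at PND35, 19 averaged and 10 for the difference between ages, and the mixture called 3 at PND50.

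Leaving out single pools, where the lone pool left is assumed to vary like the other groups, gave 2 to 177 for age in controls, 54 to 844 for vinclozolin at PND35, 0 to 6 for the mixture at PND50, 39 to 815 for the vinclozolin average and 49 to 764 for the mixture against the sum at PND35. It gave 38 to 186 for the difference between ages with vinclozolin and 0 to 8 with the mixture, 0 to 58 for genistein and 0 to 24 for the mixture at PND35, and 0 to 7 for the mixture average. For genistein at PND50, the genistein average and the mixture against the sum at PND50 it gave 0 to 1.

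With an estimated correlation 1 of 64 list calls was kept, and with fry 17. Over single pools left out, 970 list calls were kept, 53 were lost and 1 reversed: the mean of the proliferation list with genistein at PND50 ranged from -0.481 to 0.178, the latter without control PND50 replicate 2. With 1 control pool for each exposure, r was 0.212 for genistein and vinclozolin at PND35 and -0.0785 for genistein and the mixture at PND50. The call of Met kept its direction in 26 settings and was lost in 11 of them, with an adjusted p between 0.00973 and 0.883. Lists and named genes were not recomputed on all probe sets. No detection calls were used here, so signal over background limits dim genes only through the filter.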

Other observations

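Muscle genes differed between pools of a single group, in a test chosen after the result was seen. In the mixture at PND35, the group with the widest gap, 100% of the 19 muscle genes differed in one direction between the pools (mean difference -1.38), and in the other groups 68.4% to 100% did. That group was picked for its gap, and muscle genes vary together (estimated correlation 0.818). A share near 100% was thus favoured in advance, and any shared cause would give it. Skeletal muscle carried into the dissected glands may account for the gap, but this share cannot decide it. For an effect of the mixture with one direction at both ages, the mean over the list was 1.23 at PND35 and -0.44 at PND50. The muscle scores of the mixture pools at PND50 (-0.82 and -1.88) overlap those of the controls (-0.83 and -0.98), so this stays open.

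Milk and proliferation genes seemed to vary together between the 2 pools of a group, a relation picked by eye from 28 lists, and all tests of it were chosen after it was seen. Over the 8 groups Pearson's r of the differences was 0.847 (exact permutation p = 0.011, adjusted p = 0.0549 over 5 relations) and Spearman's rho 0.833 (p = 0.0154), with r 0.973 without the 2 farthest groups. Since replicates have no order, the correlation through the origin was also taken: 0.855 (95% interval 0.378 to 0.973), with a sign-flip p of 0.0703. Among all 378 pairs of lists 3, this one included, were as large, and the adjusted p by sign flips was 0.808, so the relation did not pass. A sign flip over 8 groups can give no p under 0.00781. A single pair could thus not pass when adjusted over 378 pairs, and this test cannot decide. The explanations tried could not be excluded with 8 differences: the share of epithelium (luminal with proliferation 0.254, interval -0.549 to 0.813), muscle (muscle with milk 0.0227, -0.693 to 0.716) and cycle or hormonal state, which may differ between pools (hormone-sensing with milk 0.0331, -0.688 to 0.721; estrogen-responsive with milk -0.416, exact sign-flip permutation p = 0.312).

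The age comparison averaged over treatments called 5261 genes. Of 100 splits of the ages within treatments 1, the real one, called as many, and the highest of the others called 2419. A random division of the pools is thus an unlikely source, though 1 of 100 is the smallest share these splits can give. They do not separate age from the muscle score, which also differs between the ages. The averages over ages have 18 splits each, too few for a share under 0.05. The real value was 93 for vinclozolin, reached by 1 split, with 52 the highest of the others. It was 0 for genistein, where all 18 splits called as many and the highest other called 0, and 0 for the mixture, where all 18 called as many and the highest other called 2.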
